A study of Homo sapiens with 6 samples.

How the data were processed

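Total RNA from SH-SY5Y cells was profiled on 6 one-colour Affymetrix expression arrays, 3 from untreated cultures and 3 from cultures given 100 µM manganese for 24 h. Per the labels, the cells were kept in MEM and F12 medium with 10% fetal bovine serum, and biotin-labelled cRNA was made from 6 µg of total RNA. The labels call the arrays of a group biological replicates, numbered 1 to 3, and do not say whether cultures were started or arrays were run on the same day. The authors deposited log2 expression values for 49395 probe sets, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA subtracts background, sets the probe intensities of all arrays to one distribution and summarizes the probes of a probe set. A shift of total RNA content shared by most genes is removed by that step. The software versions, scan dates and raw intensities are not given in the sources used here.

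Of the 49395 probe sets, 102 were Affymetrix controls and were kept only for quality checks. Gene names came from the platform annotation. It gave 1 gene symbol for 44988 probe sets and several for 1832, and 2473 are unnamed here. Of those with 1 symbol, 44961 matched the human RefSeq gene table (GRCh38.p14) by Entrez number, and 0 symbols changed in the update. That table was used only for names and gene classes. The array files name no genome build, so no coordinates are given.

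A probe set was kept if it lay above the 40th percentile of its array on at least 3 of the 6 arrays. That left 29871 probe sets, 27411 of them with 1 gene. The probe set with the highest mean over the 6 arrays stood for each gene, so 13407 of 18132 genes were tested. For 7133 genes more than 1 probe set passed the filter. Where the passing probe sets of a named gene differed in sign or by more than 0.5 on the log2 scale, their range is given. Arrays give no counting depth, so the number of arrays limits the precision.

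The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with neither a trend nor robust estimation), with group as the only term. Tests are two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 13407 genes, and the threshold was an adjusted p of 0.05. Log2 fold changes are manganese minus control, and their standard errors and 95% intervals come from the same fit. Group means are log2 values ± SD with n = 3.

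The test, the threshold, the gene lists, the rule for named genes and the alternative settings were fixed before the data were examined. The 35 lists held 888 different genes. Of these, 755 were measured, 66 were too dim to pass the filter and 67 are not analysed here. Lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 35 lists. Camera compares the members of a list with all other genes. The same lists were tested with a correlation estimated from the data, and with fry, which asks whether the members of a list move on balance one way. Medians of lists carry 95% bootstrap intervals over member genes from 10000 resamples. Genes are not independent replicates, so these intervals describe the list, not the cultures.

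The genes named were chosen by a fixed rule. It took the 15 largest changes in each direction among genes past the threshold whose 3 manganese arrays all lay above or all below the 3 control arrays. Where fewer than 10 genes passed in a direction, the genes with the smallest unadjusted p filled the number up to 10. The rule also allowed up to 4 members of each list, those past the threshold first and then by unadjusted p. Fewer were taken from lists that did not pass, and not all of those are named below. It also took 18 genes of metal handling and stress whatever their values. Of those 18, 16 were measured and the others are not analysed here. Genes of probe sets annotated to several genes were not named by the rule. Transcripts that mark sex were not named.

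The alternative settings changed the filter on dim probe sets, the variance model, array weights, array scaling, the rule for several probe sets, the fold threshold, the list test and the replicate block, and left out each array in turn. After the Affymetrix spike-in controls had been looked at, 2 alternatives were added. One put spike-in level into the fit as a term, with control 1 and control 3 against the other arrays. The other compared the manganese arrays with control 2 alone. In that fit the single control is assumed to vary like the manganese arrays. Both alternatives give the same log2 fold changes, since control 2 is the only control at the spike-in level of the manganese arrays. They are therefore not 2 separate checks.

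The scripts were tested on simulated arrays drawn from the means and residual variances of the 13407 genes, with 200 genes changed in each of 20 simulations. For manganese against control, 29.3% of genes changed by 0.58 on the log2 scale, 72.3% of those changed by 1 and 95.8% of those changed by 2 were recovered. False calls made up 4.66% of calls. A hypoxia list shifted by 0.3 was called in 20 of 20 simulations, and 6 calls were made on unshifted lists over all simulations. Simulated genes were independent, which real genes are not. Each gene also had 1 variance on all simulated arrays, whereas the real controls varied more than the manganese arrays. With 200 changed genes the adjusted threshold is easier to reach than with few. The rates recovered may therefore be too high for this comparison. Figures were drawn with matplotlib 3.10.9.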

Results

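Gene expression was profiled in SH-SY5Y cells, a human neuroblastoma line with noradrenergic, neuron-like features that often stands in for catecholaminergic neurons. The series holds 3 arrays from untreated cultures and 3 from cultures exposed for 24 h to 100 µM manganese, a dose the labels give as the median lethal concentration divided by 5. Manganese is an essential metal that is toxic to the basal ganglia in excess. The comparison asks which transcripts differ between exposed and untreated cells at this dose. Over the 13407 genes tested, the manganese arrays correlated with each other at r = 0.993 to 0.996 and the controls at 0.975 to 0.992 (Pearson, across genes, which are not independent replicates). Control 1 stood apart from the other arrays, with r between 0.967 and 0.981. The first principal component held 58.5% of the variance and placed control 1 at -39.5, control 3 at -6.69, control 2 at 7.66 and the manganese arrays between 5.21 and 19.0. The 12 probe sets for poly(A) spike-in RNA, which is added to the sample before labelling, averaged 5.98 on the log2 scale in control 1 and control 3 and 7.83 in control 2 and the 3 manganese arrays. Of the controls, only control 2 therefore shared the spike-in level of the manganese arrays, and medians against control 2 alone are given for the lists past the threshold. For single genes the value against control 2 is given where it turned sign or fell below 0.5 of the main one, and for some others. The difference between 3' and 5' probe sets, a measure of RNA integrity, lay between 0.67 and 0.73 for GAPDH but between 3.51 and 3.77 for ACTB on the 6 arrays, with control 1 at 0.72 and 3.69.

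**Figure D1:**
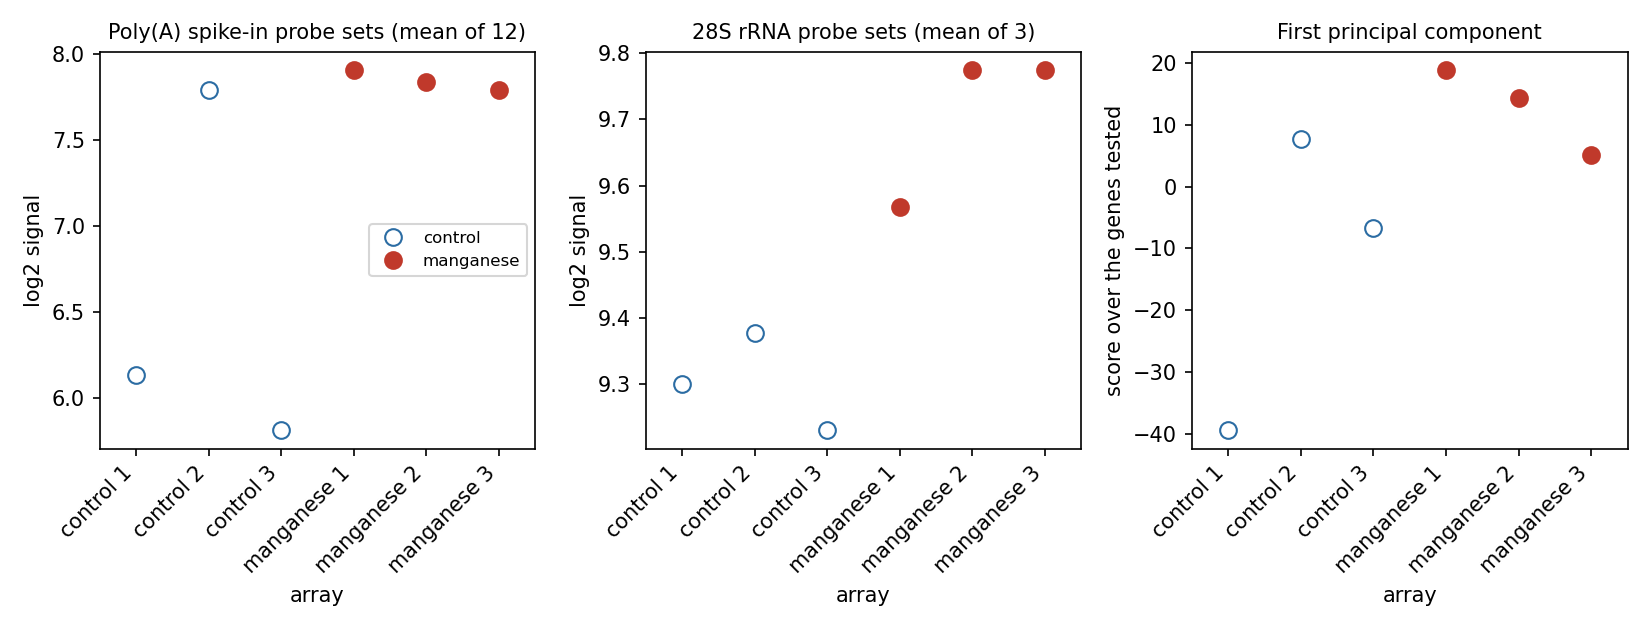
Mean log2 signal of the 12 poly(A) spike-in probe sets, mean log2 signal of the 3 probe sets for 28S ribosomal RNA, and score on the first principal component, with 1 point per array and manganese filled. Control 1 and control 3 lie at 6.14 and 5.81 in spike-in signal against 7.79 to 7.91 on the other 4 arrays, and control 1 lies at -39.5 on the first component.

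In manganese-exposed cells 18 genes were higher and 1 was lower than in untreated cells, out of 13407 tested. The 18 included 3 small nuclear and nucleolar RNAs, 6 replication-dependent histone genes, the metallothionein MT3 and the stress-inducible transcription factor ATF3, and the largest increases were those of SCARNA14, SNORA23 and H2BC9. The 18 increases ranged from 0.85 to 3.37 on the log2 scale, and 16 of the 19 changed genes differed at least 2-fold. PDRG1, which encodes a prefoldin-like protein, was the gene that fell. All 19 had non-overlapping groups. Among all tested genes, 19.8% had non-overlapping groups. Averaged over all splits of the arrays into 3 and 3, that share is 10% whatever the data, barring ties. Genes vary together, so a single split can lie far from the average. The share was not computed for the other splits, so it cannot be read as an excess over chance. At an unadjusted p under 0.05, 801 genes were higher and 918 lower. The count of 19 rested on each of 4 arrays. Without control 3 or without any 1 manganese array limma called 0 genes, with 832 to 1223 at an unadjusted p under 0.05. Without control 2 it called 43 genes, with 3010 at an unadjusted p under 0.05. Centring each array on its median gave 38 genes higher and 12 lower, and centring on housekeeping genes gave 122 higher and 81 lower. Against control 2 alone the direction of the 19 genes was fixed in advance by the lack of overlap, but the size of the change was not. It was 2.45 for SCARNA14 and 1.06 for TNFRSF12A, against 3.37 and 1.55 with all controls. MT3, at 1.75, and PDRG1, at -0.81, kept their size, and CREB5 was at 1.79 against 1.52. With spike-in level as a term the fold changes are the same as against control 2, and 2 genes passed.

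**Figure D2:**
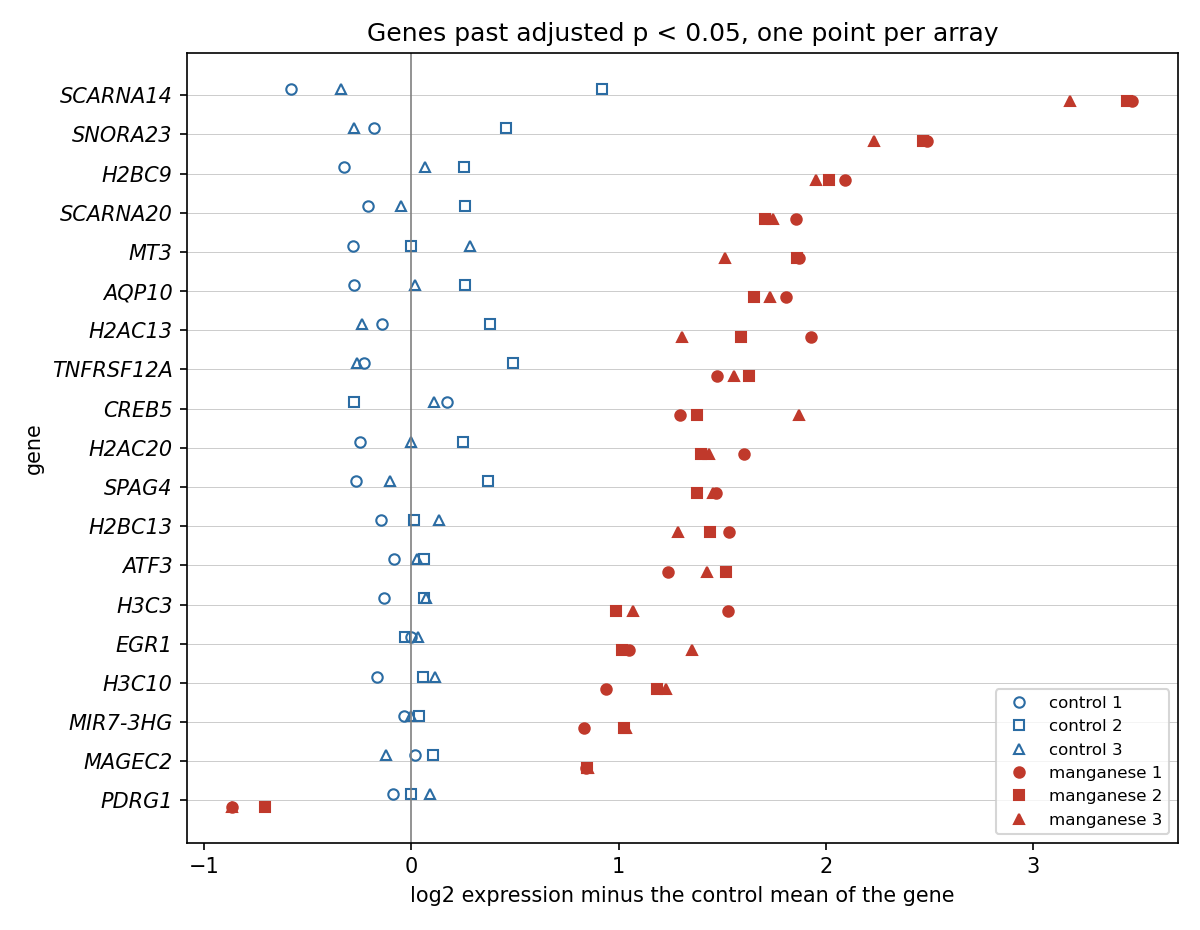
Log2 expression of the 19 changed genes on each array, minus the control mean of the gene, with open symbols for control arrays and filled symbols for manganese arrays. In every gene shown the 3 manganese arrays lie on 1 side of the 3 controls, and the spread of the controls is widest for SCARNA14, where control 2 is the highest control.

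The 2 largest increases among the changed genes were those of noncoding guide RNAs, SCARNA14 and SNORA23. SCARNA14, a small Cajal body RNA of the class that guides modification of spliceosomal RNAs, rose from 6.19 ± 0.81 to 9.56 ± 0.17 (SD, n = 3), a log2 fold change of 3.37 with an SE of 0.35 and a limma adjusted p of 0.0167. It is read by 2 probe sets, which gave 3.37 and 3.41. Against control 2 its change was 2.45. SNORA23, an H/ACA nucleolar RNA, rose by 2.40 (SE 0.20, adjusted p 0.00597) and by 1.94 against control 2. SCARNA20 rose by 1.77 (SE 0.14, adjusted p 0.00597), but its 3 probe sets ranged from 0.00 to 1.77. SCARNA14 and SNORA23 were the 2 genes that passed with spike-in level as a term. On the control arrays SNORA23 lay below the 40th percentile of its array, so its level there was close to background and its fold is limited by it.

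Replication-dependent histone genes, whose mRNAs normally end in a stem-loop and not in a poly(A) tail, were higher as a group. In the list fixed beforehand 14 of the 15 measured members had positive changes, with a median of 0.38 (95% bootstrap interval 0.06 to 0.68) and a camera adjusted p of 1.28e-06. With an estimated correlation the list did not pass, at an adjusted p = 0.278. Within the list H3C10 passed the gene test, with a log2 fold change of 1.12 ± 0.13 (SE), and 8 members passed when adjusted over the list alone. H2AC4 at 0.85, H3C4 at 0.78 and H2AC11 at 1.02 did not pass over all genes. The median against control 2 was 0.27 (-0.05 to 0.59). Outside the list, H2BC9 rose from 8.66 ± 0.30 to 10.68 ± 0.07, a 4.06-fold difference with an adjusted p of 0.00597, and by 1.77 against control 2. H2AC13 rose by 1.61, H2AC20 by 1.48, H2BC13 by 1.42 and H3C3 by 1.20. On all 3 control arrays H2BC13, H3C3, H3C10 and H2AC4 lay below the 40th percentile of their array, so their levels there were close to background and their folds are limited by it. Histone genes have near-identical copies, and the probe sets of H2AC13 and H3C10 are marked as shared, so the copy that each signal comes from is uncertain. The 6 probe sets for ribosomal RNA, which also lacks a poly(A) tail, were 0.05 to 0.84 higher in manganese, and 2 of them had non-overlapping groups. Their means were 0.40 higher for 28S and, with overlapping groups, 0.44 higher for 18S, or 0.33 and 0.37 against control 2.

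Of the other 9 genes that rose, MT3 changed most. MT3, a metal-binding protein enriched in neurons, rose from 6.49 ± 0.28 to 8.24 ± 0.21, a 3.36-fold difference with an adjusted p of 0.0126. Its 2 probe sets gave 1.38 and 1.75, and against control 2 the change was 1.75. The probe set with 1.75, which stands for MT3, is marked as shared, so other genes may add to its signal. AQP10, a water and glycerol channel, rose by 1.73 (adjusted p 0.00597) and by 1.47 against control 2, although its other probe set gave -0.05. TNFRSF12A, the receptor of the cytokine TWEAK, rose by 1.55 and was 1.06 higher against control 2. CREB5, a transcription factor that binds cAMP response elements, rose by 1.52, with 0.61 at its other probe set. SPAG4, a SUN-domain protein, rose by 1.44. MIR7-3HG at 0.96 and MAGEC2, a cancer-testis antigen, at 0.85 also rose and are named although outside the rule, after their values had been seen. PDRG1 fell by 0.81 (SE 0.11, adjusted p 0.0488) and by the same amount against control 2. At a limma adjusted p under 0.10 there were 31 genes, 27 higher and 4 lower. The lower genes next in line by unadjusted p did not pass the threshold. They included RUBCN at -0.74 (adjusted p 0.0684), ATP6V0A2, a subunit of the vacuolar proton pump, at -0.65, C6orf52 at -1.12, TNFRSF25 at -0.75, and RET, the receptor tyrosine kinase for the GDNF family of neurotrophic factors, at -1.09 (adjusted p 0.107). KANSL2 at -0.71, ITGAE at -1.10, TLE1 at -0.71 and CDH11 at -0.98 completed the set. CDH11 had a mean of 4.43 in manganese, close to the 40th percentile of the arrays. Probe sets of the same gene ranged from -0.74 to 0.06 for RUBCN, from -0.65 to -0.06 for ATP6V0A2, from -0.75 to -0.06 for TNFRSF25 and from -1.09 to -0.38 for RET.

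Hypoxia-inducible and glycolytic genes were higher in manganese as groups, by small amounts. In the hypoxia list 25 of 27 measured members had positive changes, with a median of 0.28 (0.10 to 0.55) and a camera adjusted p of 1.02e-07. The list did not pass with an estimated correlation, at an adjusted p = 0.278. No member passed over all genes, and 12 passed when adjusted over the list alone. The members with the smallest p were the prolyl hydroxylase gene P4HA2 at 0.66 ± 0.10 (SE), DDIT4, an inhibitor of mTOR signalling, at 0.95 ± 0.15, NDRG1 at 0.66 ± 0.11 and ADM, which encodes adrenomedullin, at 0.99 ± 0.17. VEGFA differed by 0.26 and did not pass. Probe sets ranged from -0.02 to 0.66 for NDRG1, from 0.24 to 0.99 for ADM and from -0.01 to 0.29 for VEGFA. In the glycolysis list, which shares 6 measured genes with the hypoxia list, 16 of 18 members had positive changes, with a median of 0.32 (0.18 to 0.46) and a camera adjusted p of 1.39e-06, which became an adjusted p = 0.249 with an estimated correlation. ENO1 at 0.48, ALDOC at 0.56, PFKP at 0.45 and PFKL at 0.59 had the smallest p, and 9 members passed over the list alone. The medians against control 2 were 0.31 for hypoxia and 0.29 for glycolysis.

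Immediate early genes, which neurons and other cells switch on within minutes of a stimulus, were also higher as a group. Of 23 measured members 18 had positive changes, with a median of 0.20 (0.04 to 0.46) and a camera adjusted p of 3.47e-05, which became an adjusted p = 0.249 with an estimated correlation. ATF3 rose from 6.23 ± 0.08 to 7.63 ± 0.14, a 2.63-fold difference with an adjusted p of 0.00597, and by 1.34 against control 2, while its other probe set gave 0.16. EGR1 rose from 6.88 ± 0.03 to 8.02 ± 0.19 with an adjusted p of 0.0189 and by 1.17 against control 2, and its 6 probe sets ranged from -0.06 to 1.14. JUN at 0.53 and ARC at 0.64 did not pass. The median against control 2 was 0.14. The integrated stress response list, targets of ATF4 and CHOP, had 20 of 32 members with positive changes and a median of 0.11 (-0.02 to 0.32), with a camera adjusted p of 0.0176 and an adjusted p = 0.353 with an estimated correlation. ATF3, which this list shares with the immediate early genes, was its only member past the threshold. CHAC1 at 0.81, DDIT4 at 0.95 and STC2 at 0.52 followed. DDIT3, which encodes CHOP, differed by 0.10 (95% interval -0.23 to 0.43), with -0.08 at its other probe set. At 4.59 in control arrays, DDIT3 was not far above the 40th percentile of the arrays. Without control 2 the list lost its call at an adjusted p of 0.150, and its median was 0.07 without control 1 and without manganese 2. Its median against control 2 was 0.13.

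Cell division, cholesterol synthesis, heat shock, ribosome biogenesis and noradrenergic identity lists were lower in manganese by camera, and no member of the 5 lists passed the gene test. In the G2/M list 28 of 33 members had negative changes, with a median of -0.19 (-0.38 to -0.16) and an adjusted p of 0.000288, which became an adjusted p = 0.472 with an estimated correlation. MKI67 at -0.69 (probe sets from -0.69 to -0.17), AURKA at -0.63, PRC1 at -0.63 and CCNB2 at -0.54 led it. Against control 2 these 4 were at -0.11, -0.28, -0.19 and -0.18. The list median was -0.37 without control 2, and -0.06 against control 2 alone with an adjusted p of 0.730. Heat shock genes had a median of -0.19 with 14 of 19 members negative (adjusted p 0.0101, and an adjusted p = 0.278 with an estimated correlation). HSP90AA1 at -0.84, HSPA1B at -0.36, HSPA8 at -0.50 and HSPH1 at -0.46 led them, with probe sets from -0.84 to -0.15 for HSP90AA1 and from -1.19 to -0.46 for HSPH1. Against control 2 HSP90AA1 was at -0.37, HSPA8 at -0.19 and HSPH1 at -0.18. The list median was -0.08 without control 1, and -0.11 against control 2 alone with an adjusted p of 0.285. The noradrenergic identity list had 15 of 19 members negative, with a median of -0.16 (adjusted p 0.0158, and an adjusted p = 0.353 with an estimated correlation). RET and STMN2, at -0.71, led it with ISL1 at -0.58, while DLK1 differed by 0.30 in the other direction. Against control 2 STMN2 was at -0.27 and ISL1 at -0.26. Its median against control 2 was -0.04 (adjusted p 0.179), and without control 1 it was -0.09 (adjusted p 0.0538). With spike-in level as a term, a fit that gives the same medians as control 2 alone, these 3 lists lost their calls.

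Cholesterol synthesis genes had 13 of 17 members negative and a median of -0.17 (adjusted p 0.00882, and an adjusted p = 0.353 with an estimated correlation), and 4 members passed over the list alone. IDI1 at -0.82, SQLE at -0.70 (probe sets from -0.85 to -0.21), MSMO1 at -0.63 and ACAT2 at -0.49 led the list. On the manganese arrays IDI1 lay below the 40th percentile of its array, so background limits the size of its fall. Against control 2 the median was -0.33 with an adjusted p of 1.83e-05, but without control 2 or without manganese 3 its median was -0.07 and the list lost its call, at adjusted p of 0.133 and 0.0769. It also lost it with the 60th percentile filter, at a median of -0.06 and an adjusted p of 0.0922. Ribosome biogenesis genes had 18 of 28 members negative and a median of -0.11 (adjusted p 0.0150, and an adjusted p = 0.353 with an estimated correlation), led by POLR1C at -0.50, MYC at -0.40, NOP58 at -0.56 (-0.26 against control 2) and NOP56 at -0.47. Their call was lost without control 2 (median -0.17, adjusted p 0.0634) and without manganese 3 (adjusted p 0.0674), and the median against control 2 was -0.08. With array weights, whose fit did not converge, the integrated stress response, noradrenergic and ribosome biogenesis lists also lost their calls.

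**Figure D3:**
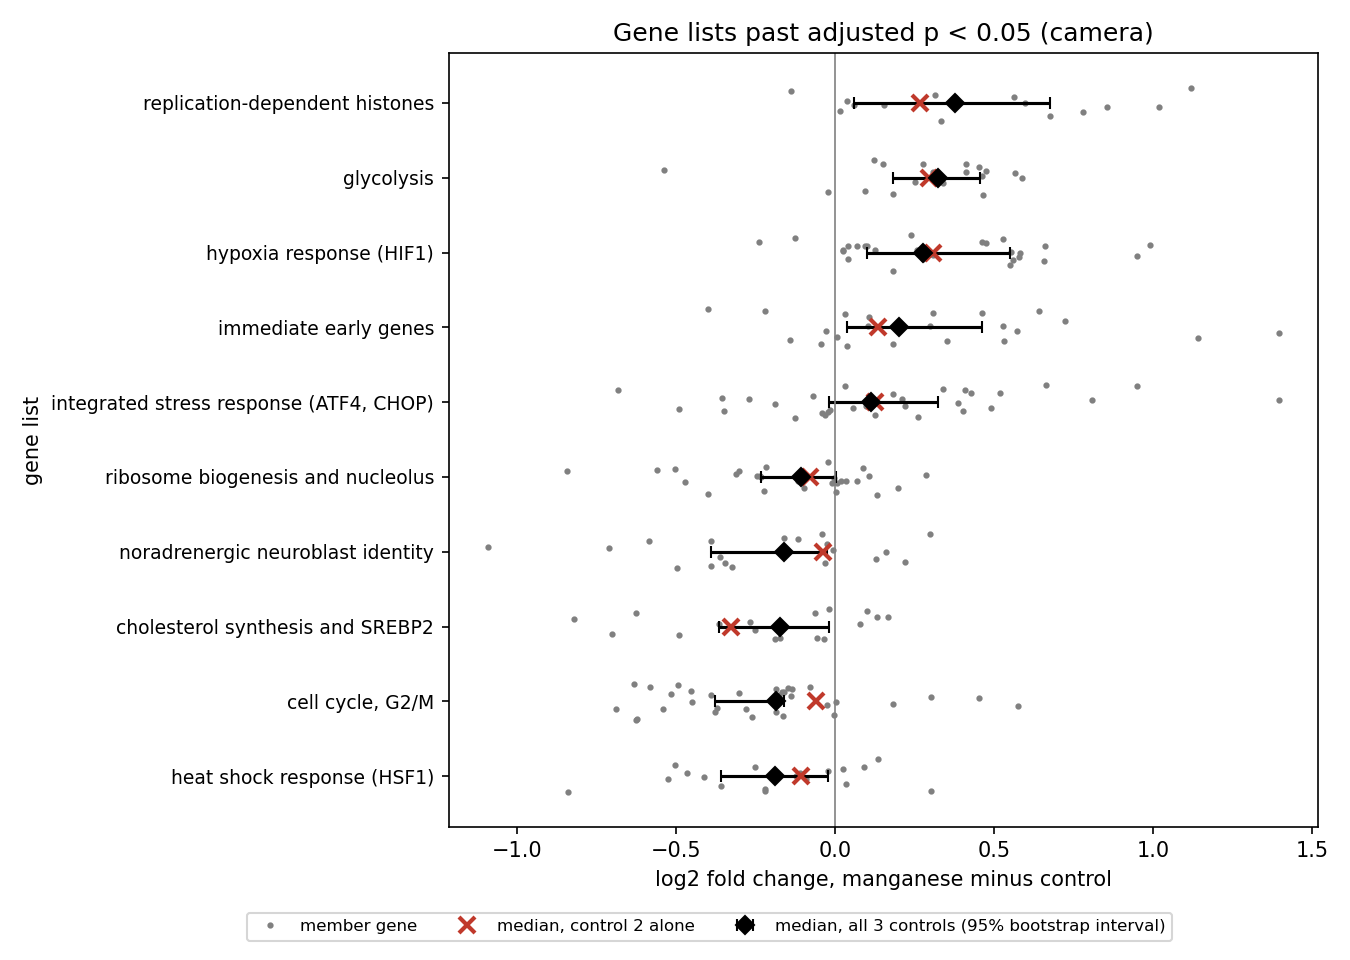
Log2 fold changes of the measured members of the 10 lists past the camera threshold (grey points), their median with its 95% bootstrap interval (black) and the median against control 2 alone (red crosses). The hypoxia median is 0.28 against all controls and 0.31 against control 2, while the G2/M median moves from -0.19 to -0.06.

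Genes known to handle manganese and other metals showed no change past the threshold apart from MT3. SLC30A10, the manganese exporter, differed by -0.03 (95% interval -0.32 to 0.26), and its level of 4.40 ± 0.15 in control arrays was close to the 40th percentile of the arrays. The importers SLC39A14 and SLC39A8 differed by -0.09 (-0.53 to 0.34) and 0.12 (-0.19 to 0.43), with -0.03 at the other SLC39A8 probe set. SLC11A2, the divalent metal transporter, differed by -0.46 (-0.86 to -0.06) with an adjusted p of 0.347 and by -0.20 against control 2. The transferrin receptor gene TFRC differed by -0.39 (-1.04 to 0.26), and by 0.23 in the opposite direction against control 2. MT2A, at 11.42 ± 0.16 in controls, differed by 0.05 (-0.23 to 0.32), and MT1X by -0.23 (-0.56 to 0.09). ATP13A2, the lysosomal transporter linked to parkinsonism, differed by 0.15, and the Golgi protein gene GOLIM4 by 0.05. GOLIM4, at 4.39 in control arrays, was also close to the 40th percentile of the arrays. The manganese enzyme gene GLUL differed by -0.15 (probe sets from -0.19 to 0.12) and TH, the rate-limiting enzyme of catecholamine synthesis, by 0.12. HMOX1, an oxidative stress marker, differed by 0.30 (0.01 to 0.60) with an adjusted p of 0.383, and CDKN1A by 0.45 (-0.04 to 0.94). Against control 2 the signs of SLC39A14 at 0.09 and ATP13A2 at -0.13 turned as well, MT2A was at -0.00, SLC39A8 at 0.06, HMOX1 at 0.12 and CDKN1A at 0.04. HSPA5, the main chaperone of the endoplasmic reticulum, was at 9.76 ± 0.43 in controls and 8.73 ± 0.26 in manganese. Its difference of -1.03 (-1.55 to -0.51) did not pass, with an adjusted p of 0.184, and its 5 probe sets ranged from -1.20 to -0.39.

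**Figure D4:**
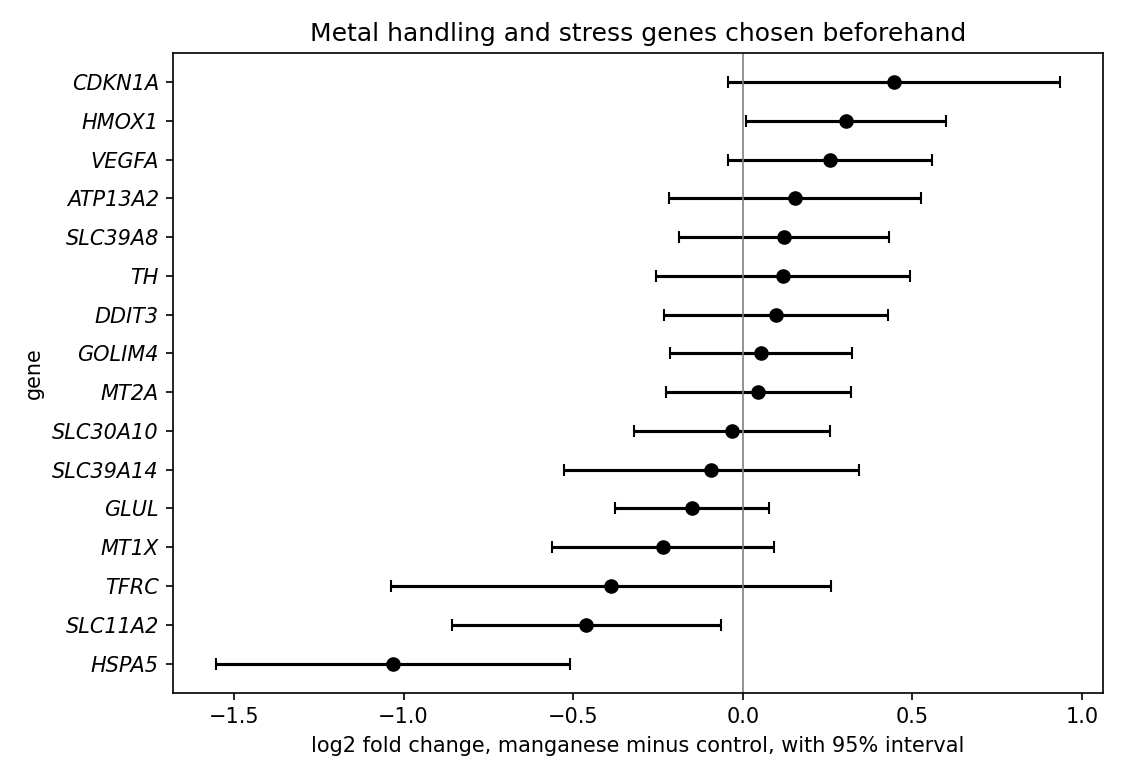
Log2 fold changes of the 16 measured metal handling and stress genes that were chosen beforehand, with 95% intervals from the limma fit. The intervals of HSPA5, SLC11A2 and HMOX1 exclude 0, and no gene passes the adjusted threshold.

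The remaining 25 lists did not pass; the number in parentheses after each median is the camera adjusted p. The metallothionein list had a median of 0.04 (camera adjusted p 0.629) with MT3 as the member that rose and MT1F at -0.43. Medians were 0.07 for manganese and divalent metal transporters (0.629), where SLC30A9 differed by 0.30, -0.09 for iron uptake and storage (0.671), where SLC25A37 differed by -0.91 (probe sets from -0.91 to -0.03) and TFR2 by 0.99, and 0.09 for manganese-dependent enzymes (0.456). NRF2 antioxidant targets had a median of 0.08 (0.0655), with SQSTM1 at 0.51 and NQO1 at 0.69, and reactive oxygen defence enzymes had one of 0.00 (0.957), with PRDX1 at -0.41 (0.02 against control 2). The NRF2 list passed by camera without control 1 (median 0.12, adjusted p 0.0101) and without manganese 1 (median 0.09, adjusted p 0.0450). It did not pass with any other single array left out. Chaperones of the endoplasmic reticulum were at -0.12 (0.0655), with HYOU1 at -0.44, proteasome subunits at -0.12 (0.0655) and splicing factors at -0.09 (0.0954). Autophagy and lysosome genes were at -0.02 (0.724), and Golgi structure and glycosylation at -0.07 (0.423). Without control 1 the chaperone, proteasome, splicing and Golgi medians were -0.03, -0.04, 0.01 and -0.00. Against control 2 they were -0.00, -0.02, 0.05 and -0.00.

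Lists of neuronal and catecholamine genes were at -0.08 for cytoskeleton, axon and synapse (0.185), with NEFM at -0.54, and 0.01 for catecholamine synthesis, storage and breakdown (0.804), where SLC18A1 differed by 0.52 and SLC6A2 by -0.54. Parkinson disease genes had a median of 0.01 (0.944), with a mean and a camera direction just below 0. Respiratory chain genes of the nucleus were at -0.01 (0.416), ribosomal proteins at 0.00 (0.626) and apoptosis regulators at 0.08 (0.944). RPL11, the ribosomal protein gene with the smallest unadjusted p, differed by -1.11 and did not pass, while 26 of 53 members had positive changes. The p53 targets were at 0.00 (0.737), with PMAIP1 at 0.74 (0.37 against control 2) and TIGAR at -0.52. TIGAR, at a mean of 4.33 in manganese, ended close to background. G1/S and DNA replication genes were at 0.02 (0.867), with CDT1 at 0.55 (0.27 against control 2). Inflammatory and NF-kB targets were at 0.13 (0.156), interferon-stimulated genes at 0.11 (0.306) and housekeeping genes at -0.02 (0.737). Extracellular matrix and adhesion genes were at -0.12 (0.629), with TIMP1 at 0.76 (probe sets from -0.02 to 0.76). Without control 1 the interferon and matrix medians were 0.02 and -0.04, and against control 2 they were -0.01 and 0.02. Markers of the mesenchymal, S-type neuroblastoma state had a median of 0.01 (0.629), with VIM at 0.77, and markers of epithelial, blood and endothelial cells one of 0.13 (0.106), with KRT19 at 0.50 (0.07 against control 2).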

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

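The tests of spike-in level for the 3 patterns, of S phase and of RNA degradation in control 1 were chosen after the results had been seen. Those of S phase, and of spike-in level for the histone pattern and for control 1, were later replaced by stricter ones, under which explanations first counted as excluded became open.

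Histone genes and small nuclear or nucleolar RNAs made up 9 of the 18 genes that rose. Spike-in level stays open. The fixed histone list kept its camera call at the preset correlation with spike-in level as a term. That fit has the same fold changes as control 2 alone, so it is no separate check. The list did not pass in the main comparison with an estimated correlation (adjusted p = 0.278). Its median against control 2 was 0.27 (-0.05 to 0.59), an interval that includes 0 and rests on a single control array. More cells in S phase also stay open. The test counted against this only if a large majority of G1/S members also shared a sign, which an unchanged list would rarely show. In the main comparison the G1/S list did not rise as a group, with a median of 0.015 (-0.09 to 0.07) over 17 positive and 14 negative members. Against control 2, a single array, its median was 0.11 (0.02 to 0.17). More RNA without a poly(A) tail being copied on the manganese arrays stays open as well. The 21 small RNA genes outside the called ones had a median of 0.28 (0.14 to 0.57), between the bounds set beforehand for and against it. A response of histone and guide RNAs to manganese was not told apart from these, so the pattern may be technical or biological.

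Hypoxia and glycolysis genes were higher together. Control 1 alone is argued against, since without it the hypoxia median was 0.37. The lowest hypoxia median with a single array left out was 0.20, without control 3, and the list still passed there (camera adjusted p 3.24e-05). Spike-in level as the whole cause is argued against by a hypoxia median of 0.31 (0.21 to 0.36) against control 2, again a single control array. A second set of hypoxia-inducible factor targets, fixed before it was tested and sharing no gene with the lists, had 18 of 23 members positive, a median of 0.31 (0.17 to 0.47) and a camera p of 1.06e-05, or 0.00824 with an estimated correlation. These values are consistent with higher activity of hypoxia-inducible factors as a hypothesis, found and tested on the same 6 arrays, and a difference in culture density or oxygen was not tested.

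Control 1 was apart from the other arrays. RNA degradation as the whole cause is argued against by 3' minus 5' differences in control 1 of 0.72 for GAPDH, within the 0.67 to 0.73 of the others, and of 3.69 for ACTB, within their 3.51 to 3.77, although each was exceeded on only 1 array. Spike-in level stays open: control 3, which has the same low level, is the array that control 1 correlates with best (r = 0.981) and is next to it on the first principal component, but lies 32.8 from it where the other 5 arrays span 25.7. No biological explanation was tested, since the labels give the controls 1 condition.

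The poly(A) spike-in probe sets were 1.86 higher on control 2 and the manganese arrays than on control 1 and control 3. The hybridisation spike-in probe sets were 0.47 higher in manganese than in controls, but 0.15 higher than in control 2, so most of this is the same split of control 1 and control 3 from the rest. The ribosomal RNA probe sets were higher in manganese by a mean of 0.40 for 28S, without overlap, and of 0.44 for 18S, with overlap. The middle 28S probe set had the largest difference of the 6, at 0.84, or 0.51 against control 2. When probe sets were the unit, 5 probe sets annotated to several genes or unnamed here passed the threshold. Of these, 2 of EIF4A2 and SNORA63 were 2.17 and 1.62 higher in manganese, 1 of SNHG15 and SNORA9 was 1.15 higher, 1 of TAF1D, SNORA8 and SNORA32 was 2.55 higher, and the unnamed one differed by -1.06.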

How the results depend on the processing

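The spike-in term and the comparison with control 2 alone, which give the same log2 fold changes, were chosen after the data were seen. Against the 19 genes changed (18 higher, 1 lower), other settings gave these counts, and the cause was not tested unless named. Spike-in level as a term gave 2 genes (2 higher, 0 lower; 558 at unadjusted p under 0.05 by limma), and control 2 alone 5 (5 and 0). Centring arrays on their median gave 50 (38 and 12) and on housekeeping genes 203 (122 and 81). These scalings and a further quantile normalization moved the median of all genes by less than 0.1. Array weights gave 3945 (1966 and 1979); their fit did not converge and weighted control 3 54.2 times control 1. Probe sets as the unit gave 32 (31 and 1), with more features tested. The lower count was 0 with the 60th percentile filter, a variance trend, the trend with robust estimation, a further quantile normalization and a fold of at least 2. Leaving out 1 array gave 0 to 43 genes (0 to 33 higher, 0 to 10 lower) and 8 to 14 lists; it gave 22 genes without control 1, 43 without control 2 and 0 without each of the other 4. The replicate numbers do not clearly pair the arrays: same-numbered arrays correlated at r = 0.967, 0.994 and 0.986. Of the manganese arrays, control 1 correlated best with manganese 3 (0.977), and control 2 and control 3 with manganese 2 (0.994 and 0.989). With the replicate block 6 genes passed (6 higher, 0 lower) and the 10 lists kept their calls. With an estimated correlation 0 of 10 lists passed (5 of 35 at unadjusted p under 0.05), and by fry 3: immediate early genes, glycolysis and histones. Camera has no robust setting, so that alternative was not run for lists. Of 339 values of the 19 genes, 207 kept their call and 132 lost it. Of 190 values of the 10 lists, 157 kept it and 33 lost it. None changed sign, which for the 19 genes was fixed wherever arrays were only left out, since their groups do not overlap. Of 1840 values of other named genes 139 gained a call, 90 of them under array weights, and 28 changed sign; of 475 values of other lists 18 gained a call and 67 changed sign. Of the 19 genes, 4 lay below the 40th percentile on all 3 control arrays, where background limits the fold.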

Other observations

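The tests below were chosen before their results were seen; the 2 classes of genes were drawn up after the called genes were known.

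Clustered histone genes, including the 15 measured members of the fixed list, and small noncoding RNAs were described as whole classes. Of 42 measured clustered histone genes 40 had positive changes and 30 had non-overlapping groups upward, with a median of 0.39 (0.34 to 0.60). Against control 2 that median was 0.27. Of 24 measured small nucleolar and Cajal body RNAs 23 had positive changes, and 16 had non-overlapping groups upward, with a median of 0.30 (0.19 to 0.73) and of 0.28 against control 2. SNORA12 followed the 3 that passed, at 1.45 and at 0.51 against control 2. SNORA33 and SNORA15 were also higher in manganese, but their control means lay below the 40th percentile of the arrays, so background limits their folds. Camera p was 2.59e-22 for histones and 6.09e-13 for the small RNAs, or 0.0412 and 0.0344 with an estimated correlation. These classes hold the called genes and the histone list, so the tests are no independent evidence of the direction.

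Lower SLBP mRNA, whose protein binds the stem-loop of histone mRNAs, was tested as a hypothesis for the histone genes. SLBP differed by -0.25 (95% interval -0.63 to 0.12, adjusted p 0.532), an interval that includes both 0 and a decrease, so the test leaves open whether lower SLBP may contribute.

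Other splits of the 6 arrays into 3 and 3 are too few for a share under 0.05, since there are 10. The real split gave 19 genes and the highest of the others 0, so 1 of 10 splits gave as many. For lists the real split gave 10 and the highest of the others 7, which was control 1, control 3 and manganese 1 against the rest, and again 1 of 10 gave as many.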
